A study of Homo sapiens with 6 samples.

How the data were processed

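RNA sequencing of HCC1599 cells was analysed from 6 libraries, 3 after washout of the γ-secretase inhibitor and 3 after mock washout, grouped by the drug treatment given in the labels. Per the labels' protocols, libraries were made from 800 ng of total RNA with integrity numbers above 9.5, and single reads of 75 bases were sequenced. The values are raw counts of reads per gene, which the authors made with featureCounts 1.5.1 of the Subread package, per the file headers, over the exons of each gene with strand option 1. The annotation was that of Ensembl release 75 on GRCh37, with ribosomal RNA and mitochondrial genes left out according to its name, per the file headers. Alignment was with STAR 2.5 to hg19, per the submitters' processing notes. The headers show that alignments were filtered before counting, but the filter is not given in the sources used here. No option for reads that align to several places or overlap several genes was set, so by the program's defaults these were not counted, which lowers the counts of near-identical copies and overlapping genes.

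Coordinates are those of the count tables, in hg19. Of 57209 gene identifiers, 51452 were named from a table of gene names and 51789 had a symbol in all; GENCODE release 29 served only for names, gene types and transcript sequence features. Totals per library ranged from 20375277 to 25217408 counted reads. Within groups, no pair of libraries was close enough in its counts to be 1 library listed again, with chi-square per degree of freedom from 1.93 to 33.59.

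The comparison was fitted with edgeR 4.0.16 in R 4.3.3 with the group as the only term. Genes were filtered with filterByExpr, which left 17872 genes and removed 39337, libraries were scaled with TMM factors, and the robust quasi-likelihood F test was adjusted after Benjamini-Hochberg with a threshold of 0.05. Fold changes are of washout over mock washout. CPM values use TMM-scaled library totals. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over the 18 lists tested. The 20 lists, fixed before the data were examined like the test, the rule for named genes and the first set of other settings, were Notch targets, Notch receptors and ligands, Notch machinery, ribosome biogenesis, G1/S, G2/M, immediate early genes, MAPK feedback, NF-κB and inflammatory genes, interferon-stimulated genes, ATF4 and amino acid genes, cholesterol genes, hypoxia and glycolysis, heat shock, luminal, basal and myoepithelial, B lymphocyte, T lymphocyte and myeloid, stromal and endothelial markers, and mitochondrially encoded mRNAs.

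The genes named were the 12 with the largest change in each direction among genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 2 and no overlap between the groups, every tested member of the Notch target, receptor and ligand lists, and up to 4 members of each other list with the smallest p. Named after their values were seen were the neighbours of CCND1, MYC and HES4, RPS27, HSP90AA1, DNAJA1, HSP90AB1, HSPB1, NCL, FBL, CCNE2, MCM5, UBE2C, FOS, JUN, DDIT3, DDIT4, KRT7, KRT8, KRT19, IFIH1 and the genes given for gene families. HSPA1A, HSPA1B, DNAJB1 and BAG3 lie outside the rule too and were named for a test of heat shock. The NF-κB list members below the filter were also named after their counts were seen.

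The other settings fixed at that time were median-ratio size factors, library totals without a composition factor, upper quartile factors, DESeq2 1.42.0, limma-voom, no expression filter, a filter at a CPM of 1 in 3 libraries, the replicate number as a block, leaving out each library, an estimated correlation in camera, and fry. Chosen after seeing the data were a fit of protein-coding genes, offsets for transcript length, GC and purine content (feature offsets), a covariate from the first component of the deviations within groups (the residual covariate), and a test against a change of 1.2-fold. The residual covariate takes spread out of the error by construction, so further calls made with it are no independent support.

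The gene test was tested on simulated counts of 17536 genes for this comparison. It called 8% of 50 genes changed 1.2-fold, 62% of those changed 1.5-fold, 78% of those changed 2-fold and 96% of those changed 4-fold, and 0.13% of 17336 unchanged genes. Of 100 random unchanged lists, 2 had a camera p under 0.05. The simulated genes were independent, had the same spread in both groups, and few of them changed. In the real data 43% of genes changed, and the estimated correlation within a list reached 0.584. The simulated rates therefore need not hold for these data, and that of camera does not cover correlated lists. Plots were drawn with matplotlib 3.10.9. Chromatin and contact data and other cell lines that the series text mentions were not analysed here. Some genes that the rule for named genes selects are not reported here.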

Results

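HCC1599 is an established human triple-negative breast cancer cell line. Total RNA was sequenced from cells in which Notch signalling was either blocked or had been released for a few hours. All cells were first held for 72 h in 1 μM compound E, an inhibitor of γ-secretase, the protease complex that frees the intracellular part of Notch receptors. After a wash they were kept for 5 h either with the solvent DMSO alone, called washout here, or again with 1 μM of the inhibitor, called mock washout. There were 3 libraries of each kind, and the question was which transcripts change when γ-secretase is released. The count tables held 57209 genes. The washout libraries held 23138170, 25217408 and 23648864 counted reads, and the mock washout libraries 20431459, 20375277 and 22386000. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

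Within 5 h of washout the cyclin D1 gene CCND1 (ENSG00000110092, hg19 chromosome 11, 69455855 to 69469242) rose 68.2-fold, from 51.9 ± 3.3 to 3543 ± 84.7 CPM (mean ± SD, n = 3 each; CPM is the usual library-scaled read count). NRARP, a feedback inhibitor of Notch signalling, rose 15.2-fold, and MYC, a regulator of growth, rose 6.62-fold from 91.5 ± 9.71 to 604.9 ± 4.05 CPM (SD, n = 3 each). The strongest fall among genes with a mean log2 CPM of at least 2 was that of BMF, a promoter of cell death of the BH3-only class, which was 17.4-fold lower after washout, with 92.7 ± 4.21 CPM under mock washout and 5.35 ± 0.801 CPM after washout (SD, n = 3 each). Genes for ribosome biogenesis, feedback of the MAPK pathway, NF-κB targets and amino acid supply rose as groups, while luminal epithelial and interferon-stimulated genes fell as groups. The G1/S list was called as rising too, but only 9 of its 22 genes rose, 2 fell and its median log2 fold change was 0.18. With Notch targets these made 8 lists called by camera with its preset correlation, of which 0 passed with an estimated correlation.

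Of 17872 genes tested with edgeR's quasi-likelihood test, 7687 changed at a Benjamini-Hochberg adjusted p under 0.05, 4015 of them higher and 3672 lower after washout. With upper quartile factors in place of TMM factors the split was 3420 higher and 4743 lower, so the balance of the directions depends on the scaling. At least 2-fold changes were seen for 801 genes that rose and 611 that fell. In 54.2% of the tested genes, 9678 in number, the CPM values of the groups did not overlap, against 10% by chance for 3 against 3. Against a change of at least 1.2-fold, a test chosen after the data were seen, 2481 genes rose and 1876 fell.

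Among genes with a symbol, a mean log2 CPM of at least 2 and no overlap of the groups, the 12 with the largest rises were CCND1, MYEOV, NRARP, ADORA2B, LIF, PLK2, ECE2, HPDL, ERVMER34-1, AEN, ANKRD1 and PRDM13. MYEOV (ENSG00000172927, hg19 chromosome 11, 69061605 to 69182494), a neighbour of CCND1, rose by a log2 fold change of 5.57 ± 0.11 (SE; edgeR adjusted p = 5.37e-10). ADORA2B, an adenosine receptor gene, rose from 3.64 ± 0.291 to 43.5 ± 1.17 CPM (SD, n = 3 each), and LIF, a cytokine of the interleukin 6 family, from 4.6 ± 1.09 to 54.5 ± 1.78 CPM (SD, n = 3 each). PLK2, a polo-like kinase gene, rose 10.9-fold to 788.1 ± 14.9 CPM (SD, n = 3). The log2 fold changes of the other 6 lay between 2.94 for PRDM13 and 3.32 for ECE2. In each of these 12 genes all 3 washout libraries lay above all 3 mock washout libraries, as the rule that picked them required.

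The 12 with the largest falls among such genes were BMF, GRB7, TNFAIP8, MYB, IL19, VASN, RBBP8NL, ITPRIP, HMGB2, PIK3IP1, SLC2A12 and ZNF209P. GRB7, an adaptor of receptor tyrosine kinases, was 4.19-fold lower, with 11.9 ± 0.419 CPM after washout and 49.9 ± 4.22 CPM under mock washout (SD, n = 3 each). MYB, a transcription factor gene, fell by 1.90 on the log2 scale (SE 0.11; edgeR adjusted p = 3.05e-07). SLC2A12, a sugar transporter gene, was 3.43-fold lower, with 104.8 ± 4.13 against 360.0 ± 10.1 CPM (SD, n = 3 each). PIK3IP1, an inhibitor of phosphatidylinositol 3-kinase, was 3.52-fold lower. HMGB2, a chromatin protein gene, was 3.53-fold lower, but its mock washout libraries spread from 51.8 to 121.4 CPM and its adjusted p was 0.0135 in the edgeR test. In each of these 12 genes all 3 washout libraries lay below all 3 mock washout libraries, which the same rule required.

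**Figure D1:**
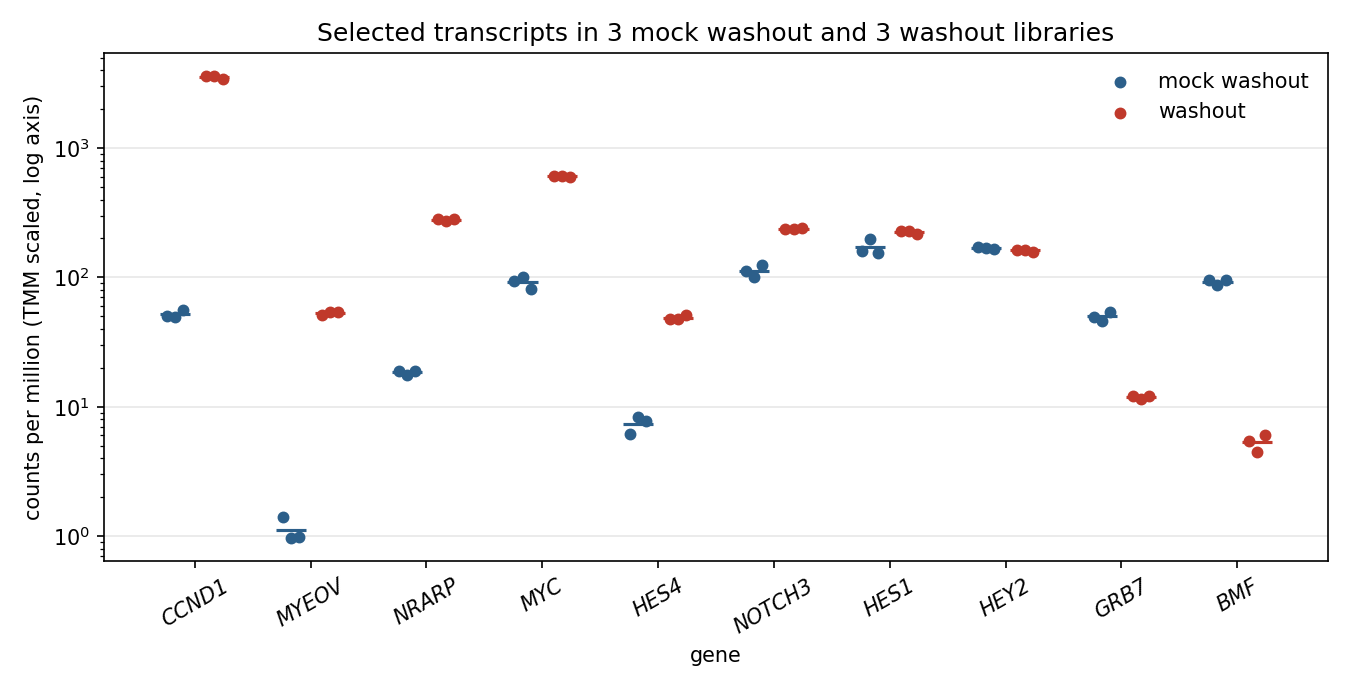
CPM (TMM scaled, log axis) of 10 genes in the 3 mock washout (blue) and 3 washout (red) libraries; each point is 1 library and each bar the mean of its group. CCND1 lies at 51.9 CPM on average under mock washout and 3543 CPM after washout, while HEY2 lies at 168.5 and 162.0 CPM.

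Classical Notch targets did not respond alike. Of the 18 genes on this list, 14 passed the expression filter. Of these 9 rose, 0 fell and 5 did not pass, with 9 rising when adjusted over the list alone (camera adjusted p = 0.000137). Its adjusted p = 0.0908 with an estimated correlation. CCND1, NRARP, MYC and HES4 led the list, HES4 rising from 7.4 ± 1.1 to 48.7 ± 1.98 CPM (SD, n = 3 each). BHLHE40 rose 2.65-fold and NOTCH3 2.12-fold. HES1, the most widely used target of Notch, rose 1.31-fold only, from 170.6 ± 23.5 to 223.9 ± 5.36 CPM (SD, n = 3 each; edgeR adjusted p = 0.00638), and IGF1R also rose 1.31-fold. HEY1 rose 1.56-fold at a level of 3.47 ± 0.272 CPM after washout (SD, n = 3; edgeR adjusted p = 0.0181). The call on HEY1 was lost without washout library 2, washout library 3 or mock washout library 1, with edgeR adjusted p = 0.0718, 0.0556 and 0.0607 (0.00113 to 0.0718 over the alternatives). HEY2 stood at 162.0 ± 3.03 CPM after washout and 168.5 ± 1.84 CPM under mock washout (SD, n = 3 each; edgeR adjusted p = 0.32), with upper quartile factors at a log2 fold change of -0.13 and adjusted p = 0.0453. SOX9 had a log2 fold change of 0.13 (edgeR adjusted p = 0.0794), which passed without mock washout library 2 at 0.17 with adjusted p = 0.00379, and with median-ratio factors (adjusted p = 0.0484; 0.000111 to 1.0 over the alternatives). HES2, HEYL and DTX1 averaged under 2 CPM in both groups and did not pass, and HES5, HES7, PTCRA and IL7R were below the filter.

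Among 9 Notch receptor and ligand genes, 4 rose, 1 fell and 4 did not pass, with the same 4 and 1 adjusted over the list alone (camera adjusted p = 0.522). NOTCH3 rose 2.12-fold, and the ligand genes DLL3, JAG1 and JAG2 rose by log2 fold changes of 0.97, 0.87 and 0.73, with 4.5% of the exon bases of JAG1 and 7.3% of those of JAG2 shared with other genes, so that both are uncertain. NOTCH1 fell by 0.34 on the log2 scale, from 178.9 ± 12.3 to 141.0 ± 0.586 CPM (SD, n = 3 each; edgeR adjusted p = 0.000567). NOTCH2 had a log2 fold change of -0.15 (edgeR adjusted p = 0.115), and passed at -0.23 without mock washout library 2 (adjusted p = 0.000228; 5.61e-06 to 0.98 over the alternatives), which made 2 falls in this list, as it also did with upper quartile factors, no filter, feature offsets or the residual covariate. The median of this list was -0.15 and its mean 0.24 on the log2 scale, and its set test pointed up. The median was not stable, at -0.08 and -0.03 without washout library 2 or 3, at -0.04 and -0.06 without mock washout library 2 or 3, and at 0.71 with the CPM filter, which left 7 members (-0.28 to 0.71 over the alternatives). Of 23 tested genes for processing, transcription complex and turnover of Notch, 5 rose, 6 fell and 12 did not pass, with 5 and 6 adjusted over the list alone (camera adjusted p = 0.808). ADAM10, which makes the cleavage before that of γ-secretase, rose 1.35-fold, as did the fucosyltransferase gene POFUT1. The coactivator gene MAML3 fell by 0.60 and the γ-secretase subunit gene APH1B by 0.75 on the log2 scale.

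Genes of the nucleolus and of ribosome biogenesis that MYC is known to activate rose almost as a block. Of 29 tested, 26 rose, 0 fell and 3 did not pass, with 27 rising when adjusted over the list alone, and their median log2 fold change was 1.32 (camera adjusted p = 1.24e-13). The list's adjusted p = 0.229 with an estimated correlation. POLR1B, a subunit of RNA polymerase I, rose 3.5-fold to 144.4 ± 2.12 CPM, NIP7 rose 2.92-fold to 51.5 ± 1.44 CPM (SD, n = 3 each), and the helicase gene DDX21 rose 2.72-fold from 315.1 ± 29.6 CPM (SD, n = 3). NCL and FBL, which code for nucleolin and fibrillarin, did not pass (edgeR adjusted p = 0.752 and 0.582), FBL passing without mock washout library 2 with a log2 fold change of 0.34 (adjusted p = 0.00285). Mock washout library 2 lay above mock washout library 3 by a median log2 difference of 0.35 over this list, with NCL at 1708 and 675.1 CPM. Without mock washout library 2, 28 members rose, and without mock washout library 3, 27.

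Of 22 genes for G1/S and DNA replication, 9 rose, 2 fell and 11 did not pass, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.0258). Its adjusted p = 0.175 with an estimated correlation. The median log2 fold change of the G1/S list was 0.18 (0.11 to 0.25 over the alternatives) and its mean 0.35. The cyclin E1 gene CCNE1 rose 3.06-fold, from 24.7 ± 1.16 to 75.5 ± 0.545 CPM (SD, n = 3 each), E2F2 rose 5.91-fold and UNG 1.62-fold. MCM5 and CCNE2 fell by 0.25 and 0.52 on the log2 scale. The call on CCNE2 was lost without washout library 2, washout library 3 or mock washout library 3 (edgeR adjusted p = 0.0843, 0.113 and 0.062), and that on MCM5 with DESeq2 (adjusted p = 0.0549). Of 22 G2/M genes, 2 rose, 6 fell and 14 did not pass, and adjusted over the list alone 2 rose and 5 fell (camera adjusted p = 0.316). Over all tested genes 43% changed, so this list held no excess of calls. Against a change of at least 1.2-fold, 0 of the 22 rose and 0 fell. CCNB1 rose 1.29-fold, and KIF11, TOP2A and CENPE fell by 0.37, 0.39 and 0.47 on the log2 scale. The other G2/M gene that rose was UBE2C (edgeR adjusted p = 0.0318). It did not pass without washout library 1, washout library 2, mock washout library 1 or mock washout library 3 (adjusted p = 0.109, 0.0722, 0.0717 and 0.0533), nor with upper quartile factors, DESeq2 or no filter (0.0554, 0.0906 and 0.0597).

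NF-κB targets and inflammatory mediators rose in 11 of 14 tested genes, 0 fell and 3 did not pass, with 11 rising when adjusted over the list alone (camera adjusted p = 1.79e-05). The count tables held 20 genes of this list. CXCL1, CCL20, IL6, TNF, IL1A and IL1B were below the filter, with at most 9 reads in any library, so the rise does not cover these mediators. The list's adjusted p = 0.0908 with an estimated correlation. The chemokine genes CXCL2 and CCL2 rose 6.11-fold and 3.07-fold, to 12.5 ± 0.599 and 24.0 ± 1.4 CPM, and NFKB1 rose 1.72-fold to 69.6 ± 2.02 CPM (SD, n = 3 each). Feedback regulators and outputs of the MAPK pathway rose in 11 of 16 genes, 0 fell and 5 did not pass, with 11 adjusted over the list alone (camera adjusted p = 1.68e-05). That list's adjusted p = 0.175 with an estimated correlation. It includes CCND1, which is also among the Notch targets, and IER3, which is also among the immediate early genes. The receptor gene EPHA2 rose 2.97-fold and the feedback inhibitor gene SPRY2 2.82-fold.

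Immediate early genes moved in both directions, 7 of 19 rising, 8 falling and 4 not passing, with 7 and 8 adjusted over the list alone (camera adjusted p = 0.537). CCN2 and CCN1, which code for matricellular proteins, rose 6.4-fold and 2.75-fold, and JUNB rose 2.28-fold, while FOS and JUN fell by 0.72 and 0.75 on the log2 scale. The median of this list was -0.02 (-0.1 to 0.04 over the alternatives) and its mean 0.29, and its set test pointed up. Among ATF4 targets and genes of amino acid supply, 13 of 18 rose, 2 fell and 3 did not pass, with 13 and 2 adjusted over the list alone (camera adjusted p = 0.00142). Its adjusted p = 0.0908 with an estimated correlation. CEBPB rose 2.78-fold, MTHFD2, an enzyme of the mitochondrial folate cycle, 2.07-fold, and the amino acid transporter gene SLC7A5 1.85-fold, while the genes that fell were DDIT3 and DDIT4, by 0.33 and 1.29 on the log2 scale.

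Luminal epithelial markers fell in 14 of 19 tested genes, 0 rose and 5 did not pass, with 15 falling when adjusted over the list alone (camera adjusted p = 2.33e-05). The list's adjusted p = 0.0908 with an estimated correlation. EHF and ELF3, epithelial transcription factor genes of the ETS family, were 2.22-fold and 1.85-fold lower, ELF3 at 651.5 ± 2.95 against 1208 ± 22.8 CPM (SD, n = 3 each; 9.2% of its exon bases are shared with another gene, so its level is uncertain), and the tight junction gene CLDN4 was 1.8-fold lower. The abundant keratin gene KRT7 fell by 0.20 on the log2 scale, and KRT19 had a log2 fold change of -0.10 (edgeR adjusted p = 0.365), which passed without mock washout library 3 at -0.17 (adjusted p = 0.0171). KRT8 fell by 0.15 (edgeR adjusted p = 0.0224), a call lost without washout library 1, 2 or 3 or mock washout library 1 (adjusted p = 0.126, 0.06, 0.125 and 0.0908). Basal and myoepithelial markers split, 3 of 16 rising, 5 falling and 8 not passing, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.808). KRT5 rose 2.11-fold, and ITGB4 and ITGA6 fell by 0.78 and 0.49 on the log2 scale. Without mock washout library 2, or with the residual covariate, 5 basal markers rose. The median of the basal list was -0.01 (-0.09 to 0.05 over the alternatives) and its mean 0.23, and its set test pointed down.

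Interferon-stimulated genes fell in 10 of 19 tested members, 0 rose and 9 did not pass, and adjusted over the list alone 10 fell and 1 rose, IFIH1 (camera adjusted p = 0.000626). Its adjusted p = 0.119 with an estimated correlation. IFI44 was 2.11-fold lower, IFIT2 1.92-fold, IFIT3 1.65-fold and the RNA sensor gene RIGI 1.57-fold. Over all genes IFIH1 had a log2 fold change of 0.14 (edgeR adjusted p = 0.0522; 0.00774 to 1.0 over the alternatives), and it passed without mock washout library 2 or mock washout library 3 (adjusted p = 0.0293 and 0.0412) and with median-ratio factors (adjusted p = 0.0356).

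Hypoxia-responsive and glycolytic genes changed without a common direction, 8 of 18 rising, 6 falling and 4 not passing, with 8 and 6 adjusted over the list alone (camera adjusted p = 0.79). The hexokinase gene HK2 rose 5.47-fold, from 38.9 ± 1.19 to 212.6 ± 1.08 CPM (SD, n = 3 each), while NDRG1 was 2.29-fold lower. Of 19 genes for cholesterol synthesis and uptake, 5 rose, 4 fell and 10 did not pass, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.796). DHCR7 and SQLE rose by log2 fold changes of 0.62 and 0.55, and FDFT1 fell by 0.74 on the log2 scale. Of 14 heat shock and chaperone genes, 3 rose, 4 fell and 7 did not pass, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.796). The mitochondrial chaperonin gene HSPD1 rose 1.92-fold. Mock washout library 2 exceeded library 3 by a median log2 difference of 0.38 over the heat shock list, with HSP90AA1 at 5932 and 2723 CPM. The falls in this list varied with the setting, with 1 without washout library 1, washout library 3 or mock washout library 1, 2 with DESeq2, 6 without mock washout library 3 and 9 with the residual covariate. For this list camera pointed down and fry, a set test of the members alone, pointed up.

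Markers of other cell types were mostly at or below the filter. Of 16 B lymphocyte markers 8 were tested, of which 2 rose, 3 fell and 3 did not pass, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.808). CR2 rose 1.93-fold and SOX11 1.25-fold. Of 15 T lymphocyte and myeloid markers 3 were tested, too few for a set test. CD7 was 1.68-fold lower (edgeR adjusted p = 0.0302), also over the list alone, with a log2 fold change of -0.46 without mock washout library 3, a call lost without washout library 1, 2 or 3 or without mock washout library 3 (adjusted p = 0.123, 0.0675, 0.0511 and 0.123), and CD14 and CD8A did not pass. Of 14 fibroblast and endothelial markers 5 were tested, of which 0 rose, 2 fell and 3 did not pass, with 3 falling when adjusted over the list alone (camera adjusted p = 0.26). KDR was 2.6-fold lower, at 2.59 ± 0.556 against 6.74 ± 0.228 CPM (SD, n = 3 each), and PDGFRA, which shares 15.8% of its exon bases with FIP1L1 and is uncertain for that reason, was 1.78-fold lower, a call lost without washout library 2 (edgeR adjusted p = 0.0505). CDH5 had a log2 fold change of -0.68 (edgeR adjusted p = 0.0527), and passed without washout library 2, mock washout library 2 or mock washout library 3 (adjusted p = 0.0446, 0.0211 and 0.0342). Mitochondrially encoded mRNAs are left out of the annotation the authors counted with, so the list of 13 such genes had 0 members in the count tables.

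**Figure D2:**
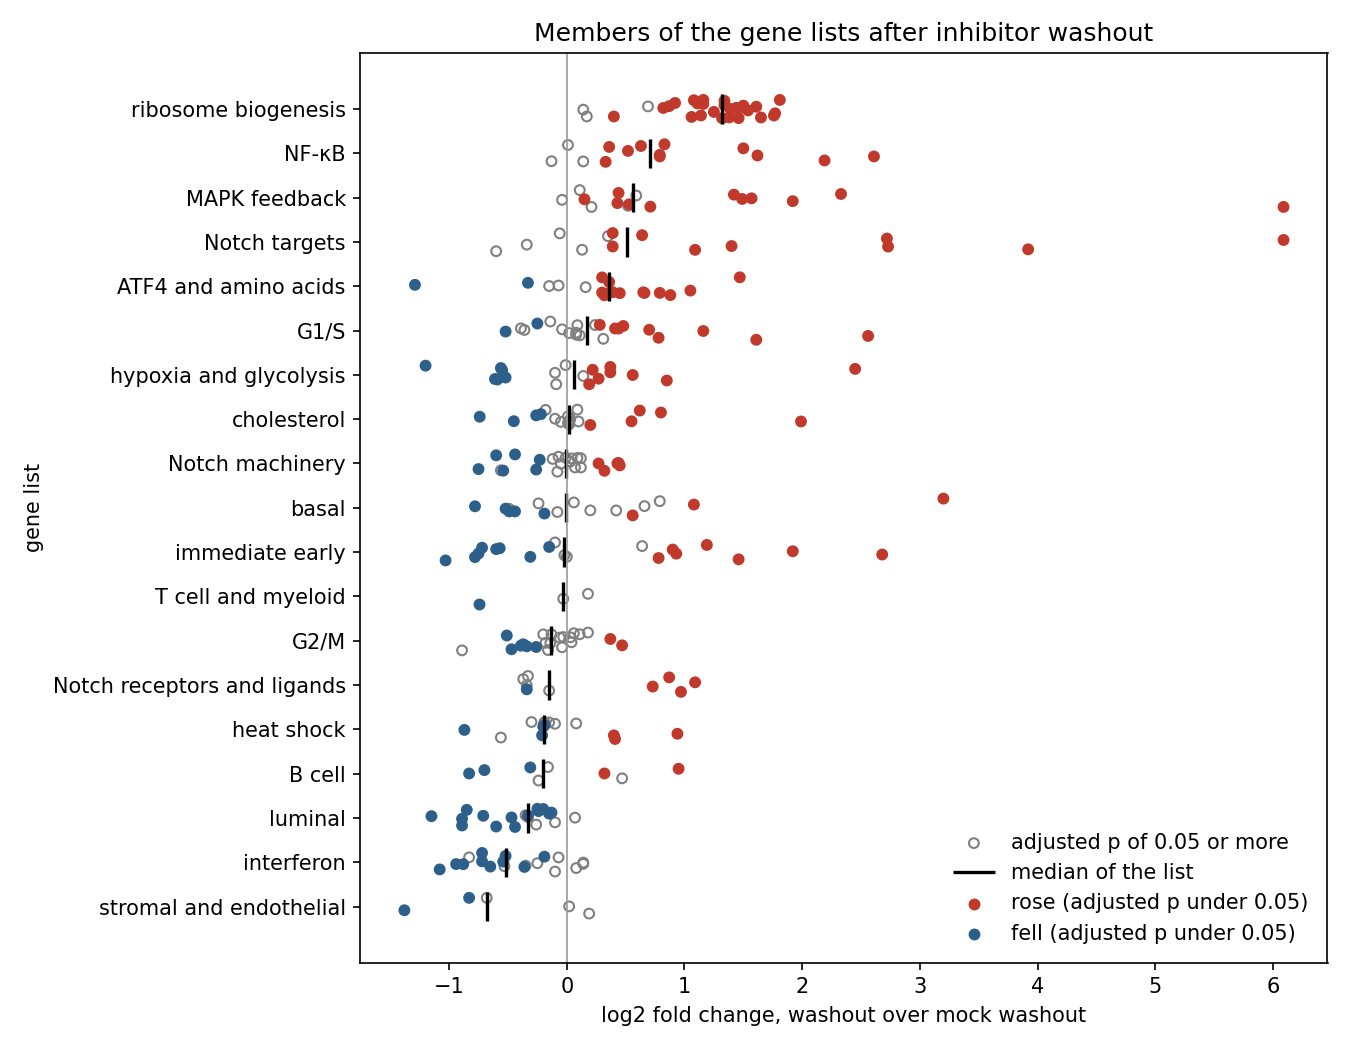
Log2 fold changes of washout over mock washout for the tested members of 19 gene lists, sorted by the median of each list (black bar). Each point is 1 gene, filled red where it rose and blue where it fell at an adjusted p under 0.05, and open otherwise; the ribosome biogenesis list lies highest at a median of 1.32.

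The series sets transcripts beside contacts between regulatory elements, so the surroundings of CCND1 and MYC are given here, chosen after their values were seen. Within 1 Mb of CCND1 the genes that rose most were MYEOV, GAL by a log2 fold change of 2.66 ± 0.27, LTO1 by 1.09 ± 0.06, TESMIN by 0.85 ± 0.06 and SHANK2 by 0.78 ± 0.06 (SE). An RNA gene without a symbol, ENSG00000260877 (hg19 chromosome 11, 69186231 to 69187279), lies just downstream of MYEOV on the same strand and rose by 3.83 ± 0.42 (SE) to 1.2 CPM. Whether its reads come from transcripts that run on past the end of MYEOV was not tested. LTO1 (69467844 to 69490184) overlaps the end of CCND1 on the other strand, and counting was by strand. It rose from 17.9 to 38 CPM, a small gain beside that of CCND1 from 51.9 to 3540 CPM. A small share of CCND1 reads counted on the wrong strand cannot be told apart from a rise of LTO1, and this was not tested. CPT1A, MRPL21 and IGHMBP2 rose by 0.33, 0.33 and 0.51, and TPCN2, ANO1, FADD, PPFIA1 and CTTN did not pass. Near MYC (hg19 chromosome 8, 128747680 to 128753674), the RNA gene PVT1 (128806779 to 129113499) rose from 24.4 to 54.2 CPM, a log2 fold change of 1.15 ± 0.09 (SE; edgeR adjusted p = 3.55e-06). PCAT1 and POU5F1B did not pass. At under 2 CPM in the mock washout libraries, CASC11, CASC8, MIR1205 and MIR1207 rose by 1.07, 0.80, 2.54 and 1.33. The last 2 lie within PVT1 on its strand, so reads of PVT1 there cannot be told apart from theirs, and they are not separate responses on these data. Each of these 4 calls was lost without some of the libraries. That on CASC11 was lost without washout library 1, 2 or 3 or mock washout library 3 (edgeR adjusted p = 0.0578, 0.0522, 0.105 and 0.0758) and with DESeq2 (0.0683). That on CASC8 was lost without washout library 1 or 3 or mock washout library 1 or 2 (edgeR adjusted p = 0.0935, 0.162, 0.109 and 0.0723) and with library totals or upper quartile factors (0.0525 and 0.0567). That on MIR1205 was lost without washout library 3 or mock washout library 1 (edgeR adjusted p = 0.0525 and 0.0565), and its log2 fold change was 4.47 without mock washout library 3. That on MIR1207 was lost without washout library 1 or mock washout library 1 (edgeR adjusted p = 0.0719 and 0.0619). An RNA gene without a symbol, ENSG00000272512 (hg19 chromosome 1, 931346 to 933431), lies just downstream of HES4 (934342 to 935552) on the same strand and rose by 3.22 ± 0.13 (SE). Reads of transcripts that run on past the end of HES4 cannot be told apart from a rise of this RNA gene, and this was not tested.

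**Figure D3:**
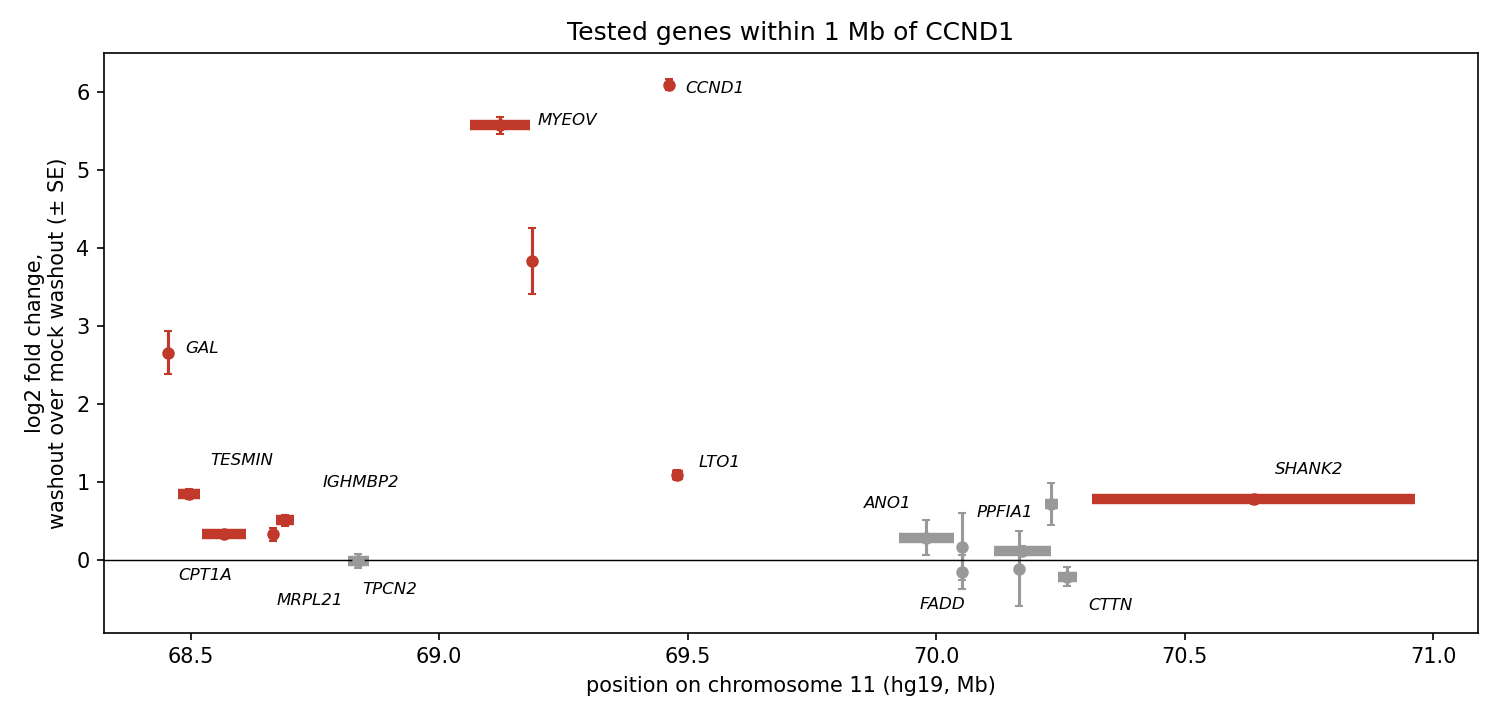
Log2 fold change of washout over mock washout (± SE) for the tested genes within 1 Mb of CCND1, against position on chromosome 11 of hg19 in Mb; each point is 1 gene and its bar the span of that gene, red where it rose at an adjusted p under 0.05 and grey where it did not pass. CCND1 lies at 6.09 and MYEOV at 5.57, while TPCN2 between GAL and MYEOV lies at -0.01.

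The mock washout libraries were less alike than the washout libraries. The median SD of log2 CPM within a group was 0.146 under mock washout and 0.084 after washout. On the first principal component, which held 66% of the variance, the groups separated, and on the next, which held 15.4%, mock washout libraries 2 and 3 lay at 31.7 and -31.1 and the other libraries between -5.8 and 4.1. Of the genes with a mean log2 CPM of at least 1, 343 were over 2-fold apart between these 2 libraries, among them the ribosomal protein gene RPS27 with 1313 and 148.7 CPM. Without mock washout library 2, 8543 genes changed, and without mock washout library 3, 8513.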

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

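The tests against a 1.2-fold change, of protein-coding genes, with transcript feature offsets and with the residual covariate were chosen only after the result was seen. Of the 7687 genes that changed, 0 changed sign under any of the alternatives run. The count was 7641 with median-ratio factors, 7673 with library totals, 8163 with upper quartile factors, 6678 with DESeq2, 7678 with limma-voom, 8280 without a filter, 7487 with the CPM filter, 6841 among protein-coding genes, 7306 with feature offsets and 10409 with the residual covariate. That covariate holds 46.1% of the deviations within groups, which form the error, so its higher count follows from how it was made. It is no check of the calls or of their signs. Leaving out 1 library gave from 6082 to 8543 genes changed, 3403 to 4490 higher, 2679 to 4083 lower, 1327 to 1662 changed at least 2-fold, and 8 gene lists changed. Against a change of at least 1.2-fold, 4357 genes passed, 2481 higher and 1876 lower, fewer because the threshold was raised. Of the 8 gene lists that changed, 0 passed with an estimated correlation, while 14 lists passed with fry, which does not compare a list with other genes. That camera setting takes its degrees of freedom from the 6 libraries, so it has little power. For Notch targets, NF-κB and ATF4 the estimate was -0.045, -0.026 and -0.008, under the preset 0.01, so correlated members do not account for these losses. For G1/S it was 0.01, as rounded equal to the preset, so a higher correlation does not account for that loss either. For luminal, interferon, MAPK and ribosome biogenesis it was 0.032, 0.033, 0.217 and 0.584, and the cause was not tested further. Over all alternatives, 2655 values of named genes kept their side of the threshold, 77 lost the call and 33 gained it, and 0 called values changed sign. Same-numbered libraries did not pair, since their deviations correlated at -0.008 to 0.063. With the replicate number as a block 7441 genes changed, 3882 higher, 3559 lower and 1410 at least 2-fold, 7177 of them also without it, and 8 gene lists; 4 of the 6 libraries correlated best with their own number, a hint from the data and not the design. The alternative without mitochondrially encoded genes was not run because 0 such genes were counted.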

Other observations

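The test of transcript features in protein-coding genes, the feature offsets, the grouping of genes by symbol and the neighbour counts by strand and beyond 100 kb were chosen only after the result was seen. When genes were grouped by the stem of their symbols into 176 families of at least 10 tested members, 12 families rose and 6 fell by camera, and 0 did with an estimated correlation (smallest adjusted p = 0.846). That setting takes its degrees of freedom from the 6 libraries and had little power over 176 families. Even NUP and UTP, where no member fell, had that value, so the 0 decides nothing about the families. With feature offsets, fitted to protein-coding genes, 13 families passed, of which MRPS had not passed before (camera adjusted p = 0.0351, and 0.0912 without offsets). The calls on HOXC, HOXA, MRPL, NAA and UBE did not pass there (camera adjusted p = 0.115, 0.101, 0.0924, 0.0755 and 0.234), and LINC, whose genes are non-coding, was not tested. The median of NAA was 0.29 there against 0.33 over the same 12 genes, with 7 rising in place of 6, that of MRPL 0.13 over 47 genes against 0.15 over 49, with 15 rising in both and 2 falling in place of 0, and that of UBE 0.10 over 39 against 0.17 over 40, with 17 rising and 7 falling in place of 19 and 4. The cause of these losses was not tested. Leaving out 1 library, without offsets, moved the families too. Without mock washout library 3 the MRPL median was 0.08, with 17 rising and 5 falling. Without mock washout library 2, 19 UBE genes rose and 8 fell. Of 33 genes with the stem POLR, nearly all of them for RNA polymerase subunits, 22 rose and 1 fell (camera adjusted p = 0.000102), POLR3G by a log2 fold change of 2.03 ± 0.14, POLR1A by 1.18 ± 0.06 and POLR2D by 1.19 ± 0.06 (SE). Of 23 genes with the stem NUP 17 rose and 0 fell (camera adjusted p = 0.000102), among them the non-coding NUP50-DT, and in a fit of protein-coding genes 16 of 22 rose. The nucleoporin genes NUP35 and NUP153 rose by 1.19 ± 0.10 and 0.73 ± 0.06 (SE). Of 11 genes of the small subunit processome (UTP) 9 rose and 0 fell (camera adjusted p = 0.000629), and of 18 cytosolic aminoacyl-tRNA synthetase genes 12 rose and 1 fell (camera adjusted p = 0.00724), IARS1 rising by 0.70 ± 0.06 (SE). The gene that fell was QARS1, and 0 of this family fell without washout library 1, 2 or 3 or mock washout library 1, with DESeq2, with no filter or with the replicate block, and 2 with the residual covariate. Without mock washout library 3, or with feature offsets, 3 POLR genes fell, and with the residual covariate 5.

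Among the families that fell, 12 of 15 protocadherin beta genes (PCDHB) were lower and 0 higher (camera adjusted p = 0.00133), PCDHB9 at -0.85 ± 0.08 and PCDHB2 at -0.74 ± 0.07 (SE). From 8 to 14 PCDHB genes fell over the alternatives. The number was 8 with DESeq2 and without washout library 2, mock washout library 1 or mock washout library 3. The family's median log2 difference of mock washout library 2 over library 3 was -0.41, beside a median change after washout of -0.79. These genes are closely related copies in tandem, so reads shared between them make their levels uncertain. Of 12 genes with the stem HOXC, which include the antisense RNAs HOXC13-AS, HOXC-AS3 and HOXC-AS2, 9 fell and 1 rose (camera adjusted p = 0.0157). With feature offsets the HOXC median stayed at -0.62, over 9 members in place of 12, and that of HOXA was -0.78 over 7 members, against -0.74 over 10, so the loss of these 2 calls cannot be put down to the offsets alone. In a fit of protein-coding genes 7 of 9 fell and 1 rose. HOXC9 had a log2 fold change of -1.27 ± 0.13 (SE). The rise of HOXC13 was lost with upper quartile factors (edgeR adjusted p = 0.0603) and without washout library 1 or washout library 3 (0.0674 and 0.0951). Of 16 genes with the stem PIK, 7 fell and 0 rose (camera adjusted p = 0.0422; 7 of 13 in a fit of protein-coding genes), among them PIK3R3 at -0.89 ± 0.05, PIK3R1 at -0.78 ± 0.07 and PIK3CA at -0.45 ± 0.06 (SE), besides PIK3IP1.

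The count of 7687 changed genes was set against explanations from the libraries. Among the 10 splits of the 6 libraries 3 against 3, 1 gave as many genes, the real one with 7687, and the highest of the others gave 0. With 10 splits the share cannot go under 0.05. Every other split holds libraries of both treatments on each side, so the change after washout adds to its spread. A low count there was therefore to be anticipated, and the gap between 7687 and 0 decides nothing about chance. Thinning each library to the smallest total left 7486 genes changed, which argues against unequal totals as the cause. Removing trends with transcript length, GC and purine content left 7306 protein-coding genes changed, against 6841 in the same genes without the offsets. These features accounted for only 1.6% of the variance of the change after washout, so the offsets could hardly lower the count. A bias between mock washout libraries lies within 1 group and adds to the spread there, so this test cannot weigh it as a cause. The values show only that the count does not rest on trends with these features. Release of γ-secretase, the difference the design names, stays open together with any other effect of the inhibitor's removal.

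Mock washout libraries 2 and 3 differed by a median absolute log2 difference of 0.17, against 0.07 between washout libraries. A candidate explanation is a preparation bias for short and purine-rich transcripts: length, GC and purine content accounted for 23.1% of the variance of the difference across protein-coding genes, and across long non-coding RNAs the purine share correlated with it at a Spearman rho of 0.228 (bootstrap interval 0.165 to 0.289; genes are not independent replicates). The same features accounted for 1.6% of the variance of the change after washout. For heat shock of library 2, the median log2 difference was 0.12 in HSPA1A, HSPA1B, DNAJB1, BAG3 and HSPH1, chosen as inducible genes. HSPA1A and HSPA1B are near-identical copies, whose counts are lowered by the counting. HSP90AA1, DNAJA1, HSP90AB1 and HSPB1 of the heat shock list differed by 1.12, 1.06, 1.04 and 0.73, and the median of that list was 0.38. The answer thus depends on the genes chosen, and heat shock is not settled. The design names no difference between these libraries, and no other biological explanation was tested.

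Genes that rose at least 2-fold lay next to each other in 118 pairs, against 35.8 on average when the rises were permuted within 10 classes of expression (permutation p = 1e-04, the smallest that 10000 draws can give), which argues against chance given the number of genes that rose. Pairs with different symbol stems numbered 90 against 30.8 (permutation p = 1e-04, the smallest they can give), which argues against tandem copies of one gene family as the whole cause. Pairs over 20 kb apart numbered 39 against 14.9 (permutation p = 1e-04, again the smallest), but 30 of them lay on the same strand, against 7.8, and 9 on opposite strands, against 7.1 (permutation p = 0.284), and over 100 kb apart there were 18 pairs against 6.8 (permutation p = 2e-04), 13 on the same strand against 3.4 and 5 on opposite strands against 3.4 (permutation p = 0.257). An excess at these distances is not what short read-through gives, but as it was seen on the same strand and not detected on opposite strands, the distance limit may not bar long transcripts that run on past a gene's end, and read-through or antisense reads from the neighbour cannot be told apart from a shared response to Notch, which was not tested. For genes that fell at least 2-fold, pairs over 20 kb apart numbered 17 against 5 on the same strand (permutation p = 2e-04) and 11 against 4.5 on opposite strands (permutation p = 0.0059), and over 100 kb 9 against 2.3 (permutation p = 8e-04) and 4 against 2.3 (permutation p = 0.194).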
